A study of Mus musculus with 6 samples.

How the data were processed

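RNA sequencing libraries were made from N1E115 mouse neuroblastoma cells kept for 3 days in 20% or 4% oxygen, with 3 libraries per oxygen level, and sequenced on an Illumina HiSeq instrument per the labels. The labels disagree on the library kit: the series' design text names a stranded total RNA kit with ribosomal RNA removal, and the extraction protocol names an mRNA kit. Histone transcripts and other RNAs without a poly(A) tail were among the counted genes. The submitters' processing notes name TopHat2 2.0.6, Bowtie, HTSeq and the mm10 build, with no role for each. The counting mode, strand use, gene annotation and treatment of reads that map to several places are not given in the sources used here.

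The deposited table gives a raw read count and an RPKM value for 23358 gene rows in each of the 6 samples, with gene coordinates in mm10 on 21 chromosomes, and no mitochondrially encoded gene is among the rows. Per the file headers, the count columns are gene counts, and 100% of the count values were even, as where both reads of a pair are counted. The authors' RPKM values are per kilobase of the deposited coding length and scaled to a library total. That total, recovered as the count divided by the RPKM and the length, was constant within each library to a relative spread of 5.11e-15 and exceeded the sum of the gene counts, so that genes held 57.6% to 67.8% of it. RPKM was used only for this check. No row lacked a gene name (0%), and 0 columns of sample values were left unmatched to a sample. Symbols that occur in several rows were kept as separate rows. Genes with near-identical copies, overlapping genes and antisense partners may share reads, and exon overlaps were measured on GENCODE mouse release M21.

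Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 14979, libraries were scaled by TMM, and the quasi-likelihood test compared 4% with 20% oxygen, two-sided, with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors were the log2 fold change divided by the square root of the F statistic. CPM values are TMM scaled. The common biological coefficient of variation was 0.359. Library measures were compared by exact two-sided permutation tests, which with 3 against 3 cannot go below 0.1. Totals ran from 124259000 to 163695000 counts, so differences between replicates, not counting error, limit the precision for all but the least abundant genes.

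Gene lists, the groups, the tests and most alternatives were fixed before the data were examined. The 21 lists covered hypoxia-inducible factor targets, glycolysis, oxygen sensing, the respiratory chain, mitochondrially encoded genes, nitric oxide signalling, histone and DNA demethylases and methyltransferases, cholesterol, cell division, stress responses, antioxidant and iron genes, sympathoadrenal and neuronal identity, markers of mesenchymal, Schwann and neural crest cells, immune and endothelial markers, interferon, p53 and immediate early genes, replication-dependent histones and abundant RNAs without a poly(A) tail. Of 670 list entries 647 matched a row, 13 of them under another name than the first: 9 by an alternative name written with the list and 4 by a synonym in the reference; 0 of the 15 mitochondrially encoded genes matched, so that list was not analysed here. The other 20 lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20. They were tested again with an estimated correlation and with fry. With an estimated correlation camera also takes its degrees of freedom from the residuals of the fit, which are few with 6 libraries. They are fewer still with a library left out or a block added. A call lost under that setting need not reflect correlation between members. With a library left out or a block added, no list passed under it. The estimated correlation with each library left out in turn was added after the results were seen. Members were also counted as adjusted over the list alone, that is, with Benjamini-Hochberg adjustment of the edgeR p-values within the list.

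The rule for named genes took up to 6 genes per direction among those called over all genes with a mean of at least 5 CPM and groups that do not overlap, which gave 0, the 2 members with the smallest p of each list (40 genes), and Nos1, Hif1a, Vegfa, Slc2a1, Kdm3a, Ldha and Egln3, which made 44 in all. Other list members named in the text are examples chosen after their values were seen.

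The labels number the libraries 1 to 3 in both groups without saying what a number marks. Deviations from the group means over genes correlated at 0.285, 0.465 and 0.233 between the libraries numbered 1, 2 and 3, and 6 of 6 libraries correlated best with the library of their own number in the other group. All 3 correlations exceed 0.1, so the numbers were taken to pair the libraries, from the data alone, and the fit with the replicate number as a block is given where it changes a call or moves a count by more than 1.5 times. Its common biological coefficient of variation was 0.277.

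Alternatives were RLE, upper quartile and total-count scaling, no filter or a filter of at least 1 CPM in 3 libraries, the replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, and glmTreat against a fold of 1.2. Added after the data were examined were halved counts, robust dispersion, leaving out 5 abundant RNAs, the block without both replicate 1 libraries, and the counts over a list alone under each setting. DESeq2 gave 11 genes no adjusted p, and these were left out of its counts. The edgeR step was tested on counts simulated from the real means and library sizes for 4% against 20% oxygen. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of less abundant genes was not measured. In a simulation without pairing, 14779 genes were tested, and 4% of 50 genes changed 2-fold, 84% of 50 changed 4-fold and 100% of 50 changed 8-fold were called. In another simulation without pairing, with the glycolysis list doubled as well and 14761 genes tested, these shares were 20%, 90% and 100%. With pairs that deviate together and no block in the fit, these shares were 0%, 70% and 100%, and with a block 8%, 92% and 98%, with 14778 genes tested in both. These pair deviations were added to dispersions that already hold those of the real pairs, so the simulated libraries vary more than the real ones. Of 14757 unchanged genes 2 were called without the block and 9 with it, against 3 and 5 in the simulations without pairing. With the glycolysis list doubled, camera called that list alone of 20 (adjusted p = 2.93e-25), and with no list changed it called 0. Simulated genes varied independently, whereas the estimated correlation in these data was 0.807 for the histone list. The simulation therefore could not show list calls that arise from correlated members. Sequence alignments used BLAST+ 2.17.0 and plots Python 3.11.15 with matplotlib 3.10.9.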

Results

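RNA was measured in N1E115 cells, a mouse neuroblastoma line with sympathetic neuron features that the labels describe as positive for NOS1, the neuronal nitric oxide synthase. The cells had been cultured for 3 days in 20% or 4% oxygen. Each oxygen level had 3 libraries, numbered 1 to 3 in both groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The 20% oxygen libraries held about 129850000, 124259000 and 139216000 counts over genes, and the 4% oxygen libraries held 130916000, 163695000 and 145889000. Library totals averaged 131110000 ± 7557700 counts at 20% oxygen and 146830000 ± 16410000 counts at 4% oxygen (SD, n = 3; exact two-sided permutation p = 0.2). With 3 libraries against 3 this exact test cannot go below p = 0.1. The question set by the labels is which transcripts differ between low and ambient oxygen.

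Pearson correlations of log2 CPM (TMM scaled) between libraries of 1 group ran from 0.955 to 0.981 across genes, which are not independent replicates. Chi-square values per degree of freedom for those pairs ran from 120 to 509, so no library was a second copy of another. Same-numbered libraries of different groups correlated at 0.965, 0.982 and 0.980, so these correlations did not separate the oxygen levels. For 20% oxygen replicate 1 they were 0.957 to 0.965 with the 4% oxygen libraries and 0.955 with both others of its group. Replicate 1 at 20% oxygen stood farthest from the rest, at -75.0 on a first principal component that held 37.6% of the variance, where the other 5 libraries lay between -27.5 and 48.9. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower at 4% oxygen among the 14979 genes tested. At an unadjusted p under 0.05, 451 genes were higher and 213 lower. These were 900 and 428 with the replicate number as a block, 885 and 460 without 20% oxygen replicate 1, 496 and 346 without 20% oxygen replicate 3, and 227 and 65 without 4% oxygen replicate 3. DESeq2 called 53 higher and 6 lower, and limma-voom called 0 in either direction. The edgeR fit with the replicate number as a block called 11 higher and 0 lower. Leaving out 4% oxygen replicate 3 made the test call 1 gene lower, Cap2, which was chosen after its values were seen and had 0, 0 and 11.4 CPM in the 4% oxygen libraries against 16.2 to 24.6 CPM at 20% oxygen. With no filter on low counts it called 25 higher and 2 lower. The 3 libraries of one group all lay above the 3 of the other for 948 genes higher at 4% oxygen (6.33%) and 557 lower (3.72%). Chance gives 10% for both directions together if all 6 libraries are exchangeable. Libraries that deviate together in pairs are not, so the 10% need not hold here.

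Targets of the hypoxia-inducible factors, the transcription factors that accumulate when oxygen is low, rose as a group at 4% oxygen. Among 45 tested targets outside glycolysis, the median log2 fold change was 0.94 and 41 estimates were above 0. Adjusted over the list alone, 24 members rose, 0 fell and 21 did not pass the edgeR test, against 0 when adjusted over all genes tested. Slc2a1, which encodes the main basal glucose transporter, averaged 49.3 ± 15.7 CPM at 20% oxygen and 184 ± 34.1 CPM at 4% oxygen (SD, n = 3). Its log2 fold change was 1.90 (SE 0.29), with an edgeR Benjamini-Hochberg adjusted p of 0.112 over all genes, 0.0222 with the replicate block and 0.000622 over the list alone. Pdk1, a kinase that restrains pyruvate entry into mitochondria, averaged 22.1 ± 11.4 and 119 ± 6.15 CPM, and Egln3, an oxygen-dependent prolyl hydroxylase, 21.7 ± 10.1 and 102 ± 4.44 CPM. Their log2 fold changes were 2.43 (SE 0.38) and 2.24 (SE 0.36). In mm10 these genes lie at chromosome 4, 119108745 to 119137329 (Slc2a1), chromosome 2, 71873272 to 71903858 (Pdk1), and chromosome 12, 54178981 to 54203874 (Egln3). Bnip3, a mitophagy receptor, went from 228 to 863 CPM, and the oxygen-dependent histone demethylase gene Kdm3a (chromosome 6, 71588972 to 71632905) from 82.6 ± 12.5 to 132 ± 20.7 CPM, a call kept only without 20% oxygen replicate 1 among the 6 fits that left out a library.

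The camera test, which sets a list against all other tested genes, called this list higher with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 1.3e-48). With an estimated correlation the adjusted p was 0.0417, 0.45 with the replicate block as well, and 0.0503 to 0.204 when each library in turn was left out (0.087 for 20% oxygen replicate 1), so the call was lost in all 6 of those fits. No list at all passed in those fits or with the block, where few residual degrees of freedom remain. These losses therefore say little about this list. Leaving out each library in turn left between 19 and 31 members higher over the list alone. Of the 24, 18 passed in each of those 6 fits. Without 20% oxygen replicate 1, where the list mean lay above those of the other 20% oxygen libraries, 31 members were higher and 1, Tfrc, lower. Vegfa, the angiogenic growth factor (chromosome 17, 46016993 to 46032377), did not pass with all 6 libraries. Its level was 489, 118 and 160 CPM in 20% oxygen replicates 1, 2 and 3, and 279, 282 and 275 CPM in the 4% oxygen libraries. Its log2 fold change of 0.12 (SE 0.43) became 1.004 without 20% oxygen replicate 1, where Vegfa passed over the list alone (edgeR adjusted p = 0.00303). The log2 fold change was -0.22 without replicate 2 and -0.13 without replicate 3 of that group.

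**Figure D1:**
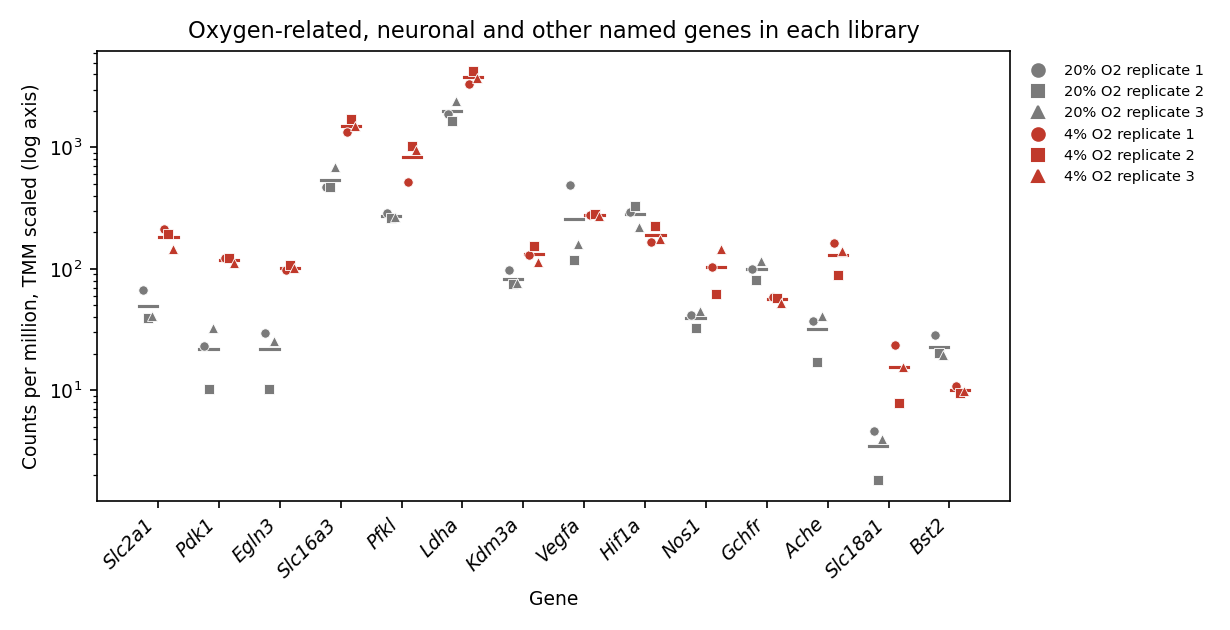
CPM (TMM scaled, log axis) of 14 genes in each of the 6 libraries, grey for 20% oxygen and red for 4% oxygen, with a marker shape for each replicate number and a bar at each group mean (n = 3). All 3 libraries at 4% oxygen lay above all 3 at 20% for Slc2a1, Pdk1 and Egln3, whereas Vegfa ran from 118 to 489 CPM within the 20% oxygen group.

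Genes of glycolysis were also higher at 4% oxygen. Of 22 tested members, 14 rose and 0 fell over the list alone, 8 did not pass, and 21 of the 22 estimates were above 0, with a median log2 fold change of 0.81. Slc16a3, a lactate exporter gene on chromosome 11 (120948484 to 120959000), averaged 541 ± 125 CPM at 20% oxygen and 1513 ± 197 CPM at 4% oxygen (SD, n = 3), a log2 fold change of 1.48 (SE 0.24). Pfkl, the liver-type phosphofructokinase (chromosome 10, 77986949 to 78009796), averaged 273 ± 15.3 and 834 ± 275 CPM, a log2 fold change of 1.61 (SE 0.28). Ldha, which encodes a lactate dehydrogenase subunit (chromosome 7, 46845804 to 46855627), averaged 1978 ± 386 and 3774 ± 462 CPM, a log2 fold change of 0.93 (SE 0.22). The edgeR adjusted p-values over the list alone were 0.00112 for Slc16a3 and Pfkl and 0.00441 for Ldha, and over all genes 0.112, 0.169 and 0.525. Eno1 passed as well, but its values are uncertain because the near-identical Gm5506 copy carried more counts, 89.5 to 270 CPM against 41.2 to 122 CPM for Eno1, and the counting could split reads between them. Gapdh, which has many pseudogenes, carries the same doubt, and its call was kept only without replicate 1 at 20% or at 4% oxygen, 2 of the 6 fits that left out a library. Camera gave an adjusted p of 3.58e-27 with the preset correlation and an adjusted p of 0.077 with an estimated correlation, so the list's call was lost there. The number of members higher over the list alone was 9 without 20% oxygen replicate 2, 7 without 20% oxygen replicate 3, and 8 without either 4% oxygen replicate 2 or 3.

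Sympathoadrenal and neuronal genes, a list of catecholamine enzymes, granule proteins and neuronal structural and receptor genes, were higher at 4% oxygen as a group by a smaller margin. The median log2 fold change of 42 tested members was 0.41, and 37 estimates were above 0. Over the list alone 4 members rose (Ache, Slc18a1, Chga and Dbh), 0 fell and 38 did not pass. Ache, the acetylcholinesterase gene (chromosome 5, 137288277 to 137294463), averaged 31.9 ± 12.9 CPM at 20% oxygen and 131 ± 37.6 CPM at 4% oxygen, a log2 fold change of 2.03 (SE 0.36; SD, n = 3). Slc18a1, a vesicular monoamine transporter gene (chromosome 8, 69037708 to 69089222), averaged 3.46 ± 1.45 and 15.6 ± 7.86 CPM, a log2 fold change of 2.17 (SE 0.46). Both had an edgeR adjusted p of 0.0222 over all genes with the replicate block, against 0.2 and 0.363 without it. Chga, a granule protein gene, had a log2 fold change of 0.91 (SE 0.23), and Dbh, which converts dopamine to noradrenaline, 0.95 (SE 0.27). Camera gave an adjusted p of 1.29e-10 with the preset correlation and an adjusted p of 0.0417 with an estimated correlation. With an estimated correlation and the block the camera adjusted p was 0.45. When each library in turn was left out it was 0.0503 to 0.204, so the call was lost in all 6 of those fits. Since no list passed in those fits or with the block, these losses say little about this list. With all 6 libraries the estimated correlation was 0.00647, below the preset 0.01, so correlation between members does not account for the larger p. The 4 calls over the list alone fell to 0 without 4% oxygen replicate 1, 1 without 20% oxygen replicate 3 and 2 without 4% oxygen replicate 3. The list mean was lowest in 20% oxygen replicate 1, at 5.264 log2 CPM against 5.594 and 5.638 in its group. Without that library camera with the preset correlation gave an adjusted p of 6.25e-06, the highest of the 6 fits that left out a library.

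Nos1 itself (chromosome 5, 117867119 to 117953813) had 41.6, 32.6 and 44.6 CPM in the 20% oxygen libraries and 103, 61.8 and 146 CPM in the 4% oxygen libraries. The group means were 39.6 ± 6.25 and 104 ± 42.1 CPM (SD, n = 3), a log2 fold change of 1.39 (SE 0.32). It did not pass over all genes with edgeR (adjusted p = 0.51, and 0.0746 with the replicate block), and DESeq2 gave an adjusted p of 0.0229. Adjusted over the list alone, it was the member of the 32 tested nitric oxide genes that passed, at an edgeR adjusted p of 0.0336. That call was kept in 1 of the 6 fits that left out a library, with adjusted p-values from 0.00443 to 0.283. Gchfr, the feedback regulator of tetrahydrobiopterin synthesis, averaged 99.0 ± 17.7 and 56.3 ± 3.39 CPM, a log2 fold change of -0.81 (SE 0.24; edgeR adjusted p = 0.0885 over the list alone). The list as a whole had a median of -0.07 and was not called by camera (adjusted p = 0.737).

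Egln1 and Egln3, prolyl hydroxylase genes of the oxygen sensor, were placed with the hypoxia-inducible factor targets, where both rose over the list alone and did so in each of the 6 fits that left out a library (Egln1 log2 fold change 1.41, SE 0.27; edgeR adjusted p = 0.0018). The list of the remaining oxygen sensing genes, which leaves them out, was not called (15 tested, median log2 fold change -0.03, mean 0.04, camera direction down; camera adjusted p = 0.522). Hif1a (chromosome 12, 73907867 to 73947530), the oxygen-regulated subunit of the main hypoxia-inducible factor, averaged 282 ± 54.7 CPM at 20% oxygen and 189 ± 30.7 CPM at 4% oxygen, a log2 fold change of -0.57 (SE 0.24) that did not pass over the list alone (edgeR adjusted p = 0.566). Hif3a averaged 1.12 ± 1.21 and 3.56 ± 2.56 CPM (log2 fold change 1.67, SE 0.87), and passed over the list alone with the replicate block (edgeR adjusted p = 0.00363 against 0.588). Its log2 fold change was 3.002 (SE 0.86) without 20% oxygen replicate 1, and between 1.09 and 2.14 without any other library. The list of histone and DNA demethylases, many of which use oxygen, had a median of 0.13 over 27 tested genes (camera adjusted p = 0.181), and 0 passed over the list alone. It also holds Alkbh5 and Fto, which act mainly on RNA, and Jarid2, which lacks demethylase activity. That list leaves out Kdm3a, Kdm4b and Kdm4c, which were placed with the hypoxia-inducible factor targets. Among those, Kdm4b passed (log2 fold change 1.14, SE 0.26; edgeR adjusted p = 0.00435 over the list alone) and was kept in all 6 fits that left out a library, Kdm3a passed (0.0312) and was kept in 1 of the 6, without 20% oxygen replicate 1, and Kdm4c did not pass (0.818). Egln1, Kdm4b and Kdm4c were named after their values were seen. With the preset correlation camera called the demethylase list higher without 20% oxygen replicate 1 (adjusted p = 0.028) or 4% oxygen replicate 1 (0.00861), and with an estimated correlation it did not (0.607 and 0.571). Tet1 averaged 4.32 ± 2.37 and 8.46 ± 2.24 CPM, and Phf2 26.9 ± 3.7 and 37.0 ± 10.1 CPM. Methyltransferases of histones and DNA had a median of -0.04 over 31 genes (camera adjusted p = 0.522), with Smyd3 at 13.4 ± 3.94 and 8.81 ± 1.27 CPM and Suv420h2 at 17.8 ± 2.1 and 24.9 ± 3.74 CPM.

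**Figure D2:**
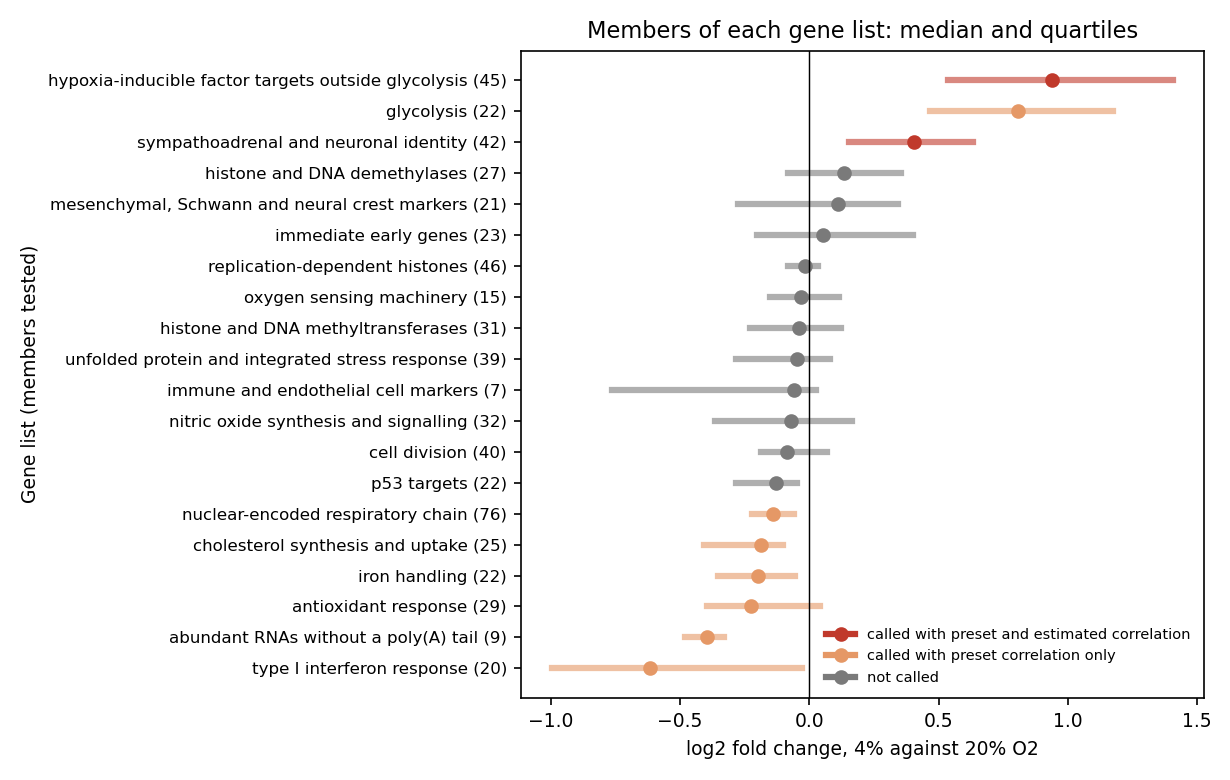
Median (point) and quartiles (bar) of the log2 fold change at 4% against 20% oxygen over the tested members of each of 20 gene lists, with the number tested in parentheses. Red lists were called by camera with the preset and the estimated correlation, orange lists with the preset correlation only, and grey lists with neither. The hypoxia-inducible factor targets had the highest median, 0.94, and the interferon list the lowest, -0.62.

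Camera called 6 lists lower at 4% oxygen with the preset correlation, and none of the 6 with an estimated correlation. Type I interferon response genes had a median log2 fold change of -0.62 over 20 tested (adjusted p = 0.000217; adjusted p = 0.485 with an estimated correlation). Over the list alone Bst2, an antiviral membrane protein gene (chromosome 8, 71534262 to 71537437), fell from 22.7 ± 4.86 to 10.04 ± 0.705 CPM (log2 fold change -1.18, SE 0.27; edgeR adjusted p = 0.0194), and lost its call without any one of the 4% oxygen libraries. With the replicate block 4 members fell over the list alone, Bst2, Ifih1, Rsad2 and Ifit1. The list mean was highest in 20% oxygen replicate 1, and without that library camera gave an adjusted p of 0.238, and without 4% oxygen replicate 2 one of 0.152. Nuclear-encoded respiratory chain genes had a median of -0.14 over 76 tested, with 63 estimates below 0 (adjusted p = 0.024; adjusted p = 0.771 with an estimated correlation), and 0 passed over the list alone. Within it, Cox4i2, a cytochrome oxidase subunit isoform, went the other way, at 7.77 ± 6.65 and 31.8 ± 2.11 CPM (log2 fold change 2.03, SE 0.59), and Ndufv3 averaged 127 ± 30.3 and 218 ± 5.23 CPM; neither passed over the list alone. For Cox4i2, DESeq2 gave an adjusted p of 0.0336 over all genes, and without 20% oxygen replicate 1 its log2 fold change was 2.88 and it passed over the list alone (edgeR adjusted p = 0.0196). Leaving out 20% oxygen replicate 3 turned the camera direction of this list (adjusted p = 0.496), and its adjusted p was 0.0907 without 4% oxygen replicate 2 and 0.127 without 4% oxygen replicate 3.

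The remaining lists that camera called lower had 0 members past the test over the list alone. Cholesterol synthesis and uptake had a median of -0.19 over 25 genes (adjusted p = 0.00344; adjusted p = 0.487 with an estimated correlation), with Idi1 at 93.5 ± 14.4 and 59.5 ± 13.96 CPM and Insig1 at 461 ± 108 and 307 ± 91.7 CPM. Its adjusted p was 0.197 without 20% oxygen replicate 1 and 0.0729 without 4% oxygen replicate 2. Antioxidant response genes had a median of -0.23 over 29 (adjusted p = 0.024), and iron handling genes a median of -0.20 over 22 (adjusted p = 0.0459), both with an adjusted p of 0.485 with an estimated correlation. Gsta4 averaged 2.63 ± 0.344 and 1.49 ± 0.2 CPM, Slc48a1 68.1 ± 10.99 and 51.6 ± 7.63 CPM, Tfr2 5.57 ± 1.15 and 8.32 ± 1.88 CPM, and Ftl1 2320 ± 318 and 1804 ± 235 CPM; other annotated genes overlap 34.6% of the exon bases of Ftl1 and 9.22% of those of Idi1, which leaves their counts uncertain. The antioxidant call was lost without 20% oxygen replicate 2 (adjusted p = 0.163) or 4% oxygen replicate 1 (0.238), and the iron call without either of these (0.353 and 0.156) or 4% oxygen replicate 3 (0.229). With the replicate block Slc40a1, an iron exporter gene, fell over the iron list alone (edgeR adjusted p = 0.0139). Abundant RNAs without a poly(A) tail had a median of -0.40 over 9 (adjusted p = 0.00365; adjusted p = 0.485 with an estimated correlation). Rn45s, the ribosomal RNA precursor, averaged 46630 ± 8409 and 34020 ± 5194 CPM, and Terc, the telomerase RNA, 120.4 ± 48.4 and 76.8 ± 12.1 CPM. One kit that the labels name removes ribosomal RNA, so Rn45s counts need not follow the level of the precursor. The camera call of this list was lost without 20% oxygen replicate 3 (adjusted p = 0.296) or 4% oxygen replicate 2 (0.0729). The 10 most abundant genes took 14.2 ± 1.4% of the counts at 20% oxygen and 11.2 ± 0.623% at 4% oxygen (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

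No change passed camera for cell division, stress or damage genes in the full set of libraries. Cell division genes had a median of -0.09 over 40 tested (adjusted p = 0.522). E2f1 averaged 53.7 ± 15.96 and 87.7 ± 21.7 CPM, and Cenpa 103 ± 35.2 and 72.4 ± 17.7 CPM. Unfolded protein and integrated stress response genes had a median of -0.05 over 39 (adjusted p = 0.247), with Nupr1 at 48.8 ± 20.7 and 31.0 ± 2.41 CPM and Psat1 at 654 ± 17.2 and 487 ± 35.1 CPM. For p53 targets the median was -0.13 over 22 (adjusted p = 0.362). Btg2, a p53-induced antiproliferative gene, averaged 17.7 ± 5.52 and 40.5 ± 11.3 CPM (log2 fold change 1.197, SE 0.31), and passed over the list alone with the replicate block (edgeR adjusted p = 0.00969 against 0.0578). Fas averaged 0.281 ± 0.0295 and 0.0772 ± 0.0545 CPM. Immediate early genes had a median of 0.05 over 23 (adjusted p = 0.362), with Klf6 at 85.8 ± 41.4 and 45.5 ± 4.32 CPM. Ier3 averaged 21.5 ± 9.88 and 52.9 ± 29.5 CPM, and passed over the list alone with the block (edgeR adjusted p = 0.00364 against 0.215). Replication-dependent histones had a median of -0.02 and a mean of -0.02 over 46, whereas camera's direction was up (adjusted p = 0.362). Hist2h4 averaged 335 ± 230.2 and 273 ± 36.5 CPM, and Hist2h2ac, with antisense overlap on 27.1% of its exon bases, 100.2 ± 62.8 and 85.7 ± 6.36 CPM.

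Libraries left out changed several of these calls. Without 20% oxygen replicate 1, the lowest library for cell division and histone genes, camera with the preset correlation called both lists lower at 4% oxygen (adjusted p = 2.58e-06 and 5.96e-11), and immediate early genes higher (0.00514). With an estimated correlation these 3 calls were lost (adjusted p = 0.485, 0.459 and 0.388). With the preset correlation the histone list was called higher without 20% oxygen replicate 2 (adjusted p = 0.00206) or replicate 3 (1.79e-06), cell division lower without 4% oxygen replicate 3 (0.0226), and the stress response list lower without 20% oxygen replicate 3 (0.0458). With an estimated correlation these 4 calls were lost as well (adjusted p = 0.853, 0.704, 0.825 and 0.704). No list passed with an estimated correlation in any fit that left out a library. Over the list alone with edgeR, members of lists other than hypoxia-inducible factor targets and glycolysis also gained a call that they did not have with all 6 libraries. Leaving out 20% oxygen replicate 1 gave the demethylase genes Kdm5b and Tet2, Th, Mx1 and Fosl2 (adjusted p = 0.00749, 0.0476, 0.0439, 0.0196 and 0.0499), all higher. Rsad2 was lower without 20% oxygen replicate 2 (0.0195), and Btg2 higher without 20% oxygen replicate 3 (0.0394). Without 4% oxygen replicate 2, Btg2 and Ier3 were higher (0.0317 and 0.0324) and Prkg2 lower (0.0389). Kdm5b, Tet2, Th, Mx1, Fosl2, Rsad2, Prkg2 and S100a4 were named after their values were seen.

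With all 6 libraries, 0 mesenchymal, Schwann, neural crest, immune or endothelial markers passed over their lists alone with edgeR. Without 20% oxygen replicate 1 Fn1 passed (log2 fold change 1.16, SE 0.23; edgeR adjusted p = 0.00809), and without 20% oxygen replicate 3 S100a4 did (0.013). Of 23 immune and endothelial markers, 7 had counts enough to test, with a median of -0.06 (camera adjusted p = 0.414). Csf1r, 15.1% of whose exon bases overlap an antisense gene, averaged 0.241 ± 0.142 and 0.138 ± 0.0401 CPM, and Tek 0.283 ± 0.0519 and 0.17 ± 0.109 CPM. Mesenchymal, Schwann and neural crest markers had a median of 0.11 and a mean of 0.00 over 21 (camera adjusted p = 0.462), with Fn1 at 82.3 ± 41.4 and 131 ± 9.47 CPM and Sox10 at 0.635 ± 0.649 and 0.266 ± 0.206 CPM. This list was called higher without 20% oxygen replicate 1 with the preset correlation (adjusted p = 0.028) and was not with an estimated one (0.42).

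**Figure D3:**
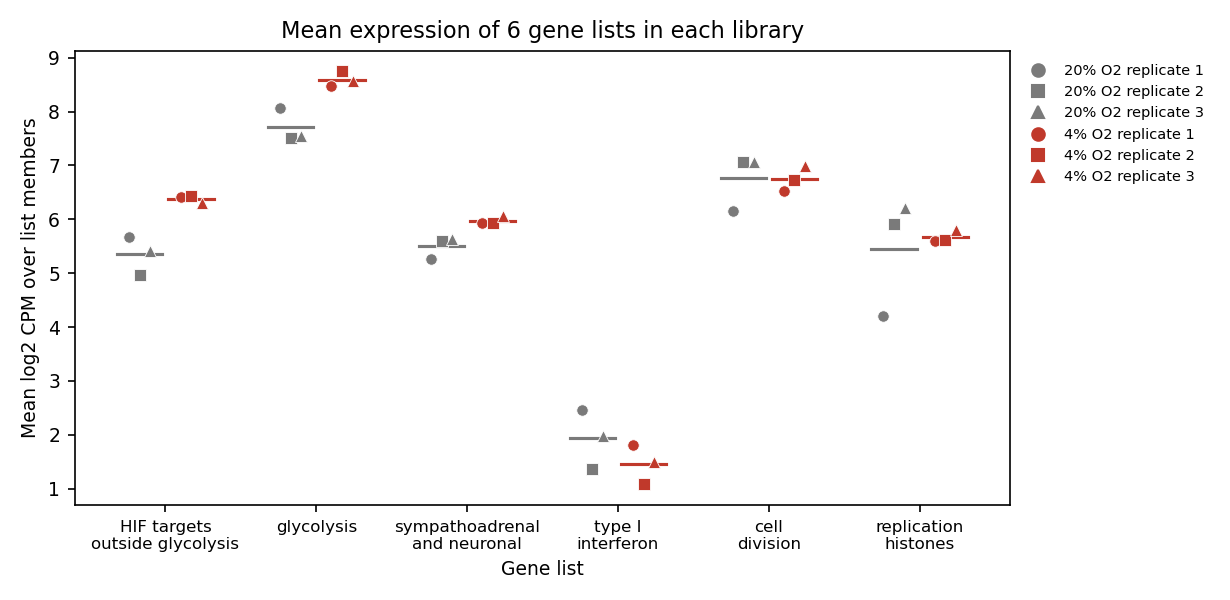
Mean log2 CPM over the tested members of 6 gene lists in each library, grey for 20% oxygen and red for 4% oxygen, with a marker shape for each replicate number and a bar at each group mean (n = 3). For hypoxia-inducible factor targets the 4% oxygen libraries lay between 6.30 and 6.43 and the 20% oxygen libraries between 4.96 and 5.67, and 20% oxygen replicate 1 was the lowest library for cell division (6.15) and replication-dependent histones (4.204).

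The 11 genes called higher with the replicate block were Slc2a1, Pdk1, Egln3, Gys1, Ache, Slc18a1, Cdh22, Kbtbd11, Sncb, Tshz2 and Kcnn3, and 10 of them were among the 59 genes that DESeq2 called without a block. 4 of the 11 belong to the hypoxia-inducible factor target or glycolysis lists, as do 19 of the 59. Gys1, Cdh22, Kbtbd11, Sncb, Tshz2 and Kcnn3 fall outside the rule for named genes and were named after their values were seen. Gys1, the glycogen synthase gene (chromosome 7, 45434839 to 45456617), averaged 35.2 ± 9.33 and 113 ± 10.9 CPM. Cdh22, a cadherin gene (chromosome 2, 165111507 to 165234737), averaged 40.3 ± 2.55 and 116 ± 20.5 CPM, and Sncb, the beta-synuclein gene (chromosome 13, 54758860 to 54766440), 7.24 ± 2.69 and 28.8 ± 4.16 CPM. Kcnn3, a calcium-activated potassium channel gene, averaged 5.1 ± 3.0 and 16.5 ± 6.58 CPM. Kbtbd11 averaged 15.9 ± 1.82 and 89.9 ± 53.9 CPM, and Tshz2 11.7 ± 4.2 and 35.8 ± 8.76 CPM; antisense genes overlap 24.8% and 67.5% of their exon bases, so without stated strand use their counts are uncertain.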

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

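Leaving out both replicate 1 libraries, halved counts, robust dispersion, 5 abundant RNAs left out and the settings of the counts over a list alone were chosen after the data were examined. Of the values for named genes, 734 kept direction and side of the threshold, 45 passed it only under the alternative and 7 turned direction. With 0 genes called in the main fit, keeping the side meant staying uncalled, and no call could be lost. Across scalings the median log2 fold change of all genes lay between -0.05 and 0.05. The edgeR counts of 0 higher and 0 lower genes stayed at 0 with the other scalings, the 1 CPM filter, limma-voom, halved counts, robust dispersion, the 0.01 threshold, glmTreat and without 5 abundant RNAs. The counts of higher, lower and at least 2-fold changed genes were 25, 2 and 27 with no filter and 53, 6 and 58 with DESeq2. The replicate block gave 11 higher, 0 lower and 11 changed at least 2-fold, and with both replicate 1 libraries left out 600, 428 and 315, on 1 residual degree of freedom. Leaving out 1 library gave 0 higher, 0 to 1 lower and 0 to 1 changed at least 2-fold. At an unadjusted p under 0.05, 634 genes were higher and 128 lower with library totals only, 474 and 320 with DESeq2, and 1638 and 1517 in the block without both replicate 1 libraries. The cause of these shifts was not tested. Camera called 3 lists higher, and 6 in the block without both replicate 1 libraries; leaving out 1 library gave 3 to 6 higher and 2 to 6 lower. The 6 lower lists became 0 with an estimated correlation and 0 with fry. Over the list alone, glycolysis had 7 to 16 members higher when 1 library was left out, and the sympathoadrenal and neuronal list 0 to 4. That list had 8 with library totals only and 7 with no filter. Library totals only ended the calls of the respiratory chain (camera adjusted p = 0.0687) and iron handling (0.0619). Iron handling also lost its call with no filter (0.0649), the 1 CPM filter (0.0713) and halved counts (0.0618). The 5 abundant RNAs left out were Rn45s, Rpph1, Rmrp, Rprl3 and Lars2, of which Lars2 is not in the list of RNAs without a poly(A) tail. Without them that list lost its call (camera adjusted p = 0.129).

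Some directions turned, and the cause was not tested. With 1 library left out, log2 fold changes ran from -2.08 to 0.0128 for Sox10 (the highest without 20% oxygen replicate 1), -0.709 to 0.339 for Hist2h4 and -0.63 to 0.297 for Hist2h2ac (the highest without 20% oxygen replicate 3), and -0.217 to 1.004 for Vegfa (also -0.127 without 20% oxygen replicate 3). Hist2h2ac was 0.00673 with the replicate block and 0.0232 with limma-voom. Camera adjusted p-values with 1 library left out, among which the direction turned, ran from 0.45 to 0.934 for oxygen sensing, 3.15e-06 to 0.496 for the respiratory chain, 0.515 to 0.997 for nitric oxide genes, 0.0773 to 0.611 for methyltransferases, 2.58e-06 to 0.708 for cell division and 0.0458 to 0.722 for the stress response. They ran from 0.028 to 0.849 for mesenchymal markers, 0.0733 to 0.987 for immune and endothelial markers, 0.0694 to 0.722 for p53 targets, 0.00514 to 0.902 for immediate early genes and 5.96e-11 to 0.823 for histones. Nitric oxide genes turned with the 1 CPM filter (0.854) and mesenchymal markers with no filter (0.736). In the block without both replicate 1 libraries, oxygen sensing (0.971), methyltransferases (0.514), the stress response (0.916), immune and endothelial markers (0.724), p53 targets (0.916) and histones (1.83e-08) turned. Fry lost the hypoxia-inducible factor target and sympathoadrenal lists with the replicate block (adjusted p = 0.194 for both, against 0.044); over the list alone the block added 10 hypoxia-inducible factor targets (24 to 34), 2 glycolysis genes (14 to 16), Phox2a and Syt1 to the sympathoadrenal list (4 to 6) and P4ha1 to the collagen-modifying enzymes (4 to 5). Beyond these changes and the results given with the block, the block changed no other call. No list passed fry with the block. At the depth of these libraries, counting error limits only genes near the lower bound of the filter.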

Other observations

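The gene groups in this paragraph and the next, the position test of 20% oxygen replicate 1 and the other matchings of the replicate numbers were chosen after the data were examined. Genes of glycogen metabolism were higher at 4% oxygen in part. Of 20 tested, 4 rose, adjusted by Benjamini-Hochberg over the group alone with edgeR: Gys1 (glycogen synthase; log2 fold change 1.68, SE 0.26), Gbe1 (the branching enzyme; 1.36, SE 0.33), Ppp1r3c (a glycogen-targeting phosphatase subunit; 2.23, SE 0.61) and Epm2a (laforin; 1.82, SE 0.48). Ppp1r3c and Epm2a belong to none of the fixed lists, and both had low levels. At 20% and 4% oxygen Ppp1r3c averaged 1.02 ± 0.9 and 4.79 ± 2.4 CPM, and Epm2a 1.21 ± 0.73 and 4.27 ± 1.3 CPM (SD, n = 3). Gys1 and Gbe1 are also hypoxia-inducible factor targets already counted as such. The number higher ran from 1, without 20% oxygen replicate 2, to 5 when single libraries were left out, and the replicate block gave 6 higher and 1 lower. Of 16 tested collagen-modifying enzyme genes, 4 were higher: Plod2, Leprel2, P4ha2 and Loxl2, with log2 fold changes of 1.38, 1.21, 1.15 and 0.77. Plod2 and P4ha2 repeat the result of the hypoxia-inducible factor target list, so 2 of the 4 add to it. That count was 0 without 4% oxygen replicate 1. Since both groups were picked from the data they were tested on, these counts describe the groups and are not independent evidence of a change.

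Among respiratory chain subunits with alternative isoforms, estimates went both ways. Ndufa4l2 averaged 21.7 ± 20.8 CPM at 20% oxygen and 142 ± 10.8 CPM at 4% oxygen (SD, n = 3; log2 fold change 2.70, SE 0.64), and Cox4i2 7.77 ± 6.65 and 31.8 ± 2.11 CPM. Their common counterparts Ndufa4 and Cox4i1 had log2 fold changes of -0.35 (SE 0.25) and -0.22 (SE 0.25) and did not pass. Cox6a2, another alternative isoform, had a log2 fold change of -1.57 (SE 0.55) and its counterpart Cox6a1 0.05 (SE 0.23), and neither passed over the group alone. Levels of Cox6a2 were low, at 1.61 ± 0.725 and 0.541 ± 0.269 CPM. Of the 14 genes in this group 3 passed over the group alone, Higd1a, Ndufa4l2 and Cox4i2. Higd1a is not itself such a subunit isoform and is counted among the hypoxia-inducible factor targets. Without 20% oxygen replicate 3 only Higd1a passed (edgeR adjusted p = 0.0045), against 0.065 for Ndufa4l2 and 0.0853 for Cox4i2. With the replicate block 4 passed as higher and 1, Cox6a2, as lower; Cox6a2 was also called lower without 20% oxygen replicate 1 or 4% oxygen replicate 2. The difference between isoforms of a pair was not tested.

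Other divisions of the 6 libraries into 3 and 3 bear on the counts above, but 10 divisions are too few for a share under 0.05. They also treat the libraries as exchangeable, although same-numbered libraries deviated together. The real division called 0 genes and the highest other count was 1; since any count is at least 0, this comparison carries no information. The sides of the other divisions have no order, so the larger of their counts in either direction was taken. The real division called 3 lists higher, where the highest other number was 7 and 10 of the 10 gave as many, and 6 lists lower, where the highest other number was 7 and 5 of the 10 gave as many. The median log2 fold change of the hypoxia-inducible factor target list was 0.94, and the largest other was -0.50, so 1 of the 10 was as large in size. With the replicate block, 4 ways of swapping oxygen levels within pairs are too few as well; the real one called 11 genes higher and the highest other 0, so 1 of the 4 was as large. Without both replicate 1 libraries, a choice made after the data were examined, the block called 600 genes higher and 428 lower. The other swap of the remaining pairs called 0. That swap turns the oxygen effect into residual variation, so its low count follows largely from the effect and gives no separate support. The same 4 libraries without a block called 0 in either direction. Of 67 hypoxia-inducible factor target and glycolysis members tested in the block without both replicate 1 libraries, 48 were called higher and 1 lower.

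Replicate 1 at 20% oxygen stood apart from the other 5 libraries, with low histone and cell division genes and a higher mean of hypoxia-inducible factor targets than the other 20% oxygen libraries. A trend in GC content or gene length took 2.35% of the variance of its deviations over the 98.5% of tested genes with a GC value, which argues against such a trend as the source. Over the 47 hypoxia and glycolysis genes called higher without this library, its median position was 0.49 on a scale from the other 20% oxygen libraries (0) to the 4% oxygen mean (1); 10 genes lay at or above the lowest 4% oxygen library, 12 at or below the highest other 20% oxygen library and 25 between, from -0.274 to 1.79 (95% bootstrap interval of the median 0.328 to 0.658, too narrow because these genes move together). The 47 genes were chosen from the libraries that set 0 and 1, so a library outside that choice tends to fall between them. The position therefore cannot decide the label. Over the whole fixed lists, replicate 1 at 20% oxygen had means of 5.67 for hypoxia-inducible factor targets and 8.07 for glycolysis. Both lay below all 4% oxygen libraries (at least 6.30 and 8.47) and above both other 20% oxygen libraries (at most 5.41 and 7.55). On these lists it was thus unlike the 3 libraries labelled 4% oxygen, and unlike its own group as well. Its correlations of log2 CPM were 0.957 to 0.965 with the 4% oxygen libraries and 0.955 with both others of its group. These values do not decide the label. A 4% oxygen culture with a weaker response, a lower oxygen exposure of this culture, its density or its growth state may account for the position and were not tested.

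Libraries with the same replicate number deviated together from their group means. After a trend in GC content and gene length was removed from each library, the smallest of the 3 same-number correlations was 0.274, so such a trend does not account for it. The real matching of numbers had a mean correlation of 0.326 and the highest of the other matchings 0.141; it was 1 of 6 as high, and 6 matchings are too few for a share under 0.05. A shared culture day or preparation could produce this, and the labels used here do not give one, so no biological explanation was tested.

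Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366940 to 123462664 in mm10), took between 0.13% and 2.34% of all counts, had an 18.3-fold range in TMM-scaled CPM, and was lowest in both replicate 1 libraries (1312 and 1862 CPM). Reads of the mitochondrial 16S ribosomal RNA counted at Lars2 are a candidate explanation, but the longest stretch of at least 50 bases that Lars2 transcripts shared with mt-Rnr2 at 90% identity was 0 bases. Other ribosomal sequences, and introns outside annotated Lars2 transcripts, were not searched. The other 16 mitochondrial tRNA synthetase genes had a median range of 1.11 on the log2 scale against 4.2 for Lars2, which argues against a change of the class as a whole. No other biological explanation was tested.

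Some genes differed at least 4-fold in a single library from all 5 others. Kctd1 had 458 CPM in 20% oxygen replicate 2 and at most 4.14 CPM elsewhere, and Zfp316 had 386 CPM there and at most 31.2 CPM elsewhere. Txnip had 2.71 CPM in the same library and at least 36.9 CPM in the others. Gria3 had 0.118 CPM in 4% oxygen replicate 3 and at least 9.45 CPM in the others. In 20% oxygen replicate 1, 10 genes lay at least 4-fold below all other libraries, among them Hist1h3b at 1.35 CPM against at least 20.2 CPM.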
